A study of Macaca mulatta with 13 samples.

How the data were processed

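Small RNA libraries were made from vastus lateralis biopsies of 5 Control and 8 CR rhesus samples. Per the labels' protocols, RNA was purified with Trizol, small fragments were isolated from a gel, libraries were made with the Illumina TruSeq small RNA kit, and reads were single-end. The genome build is Mmul_8.0.1, per the submitters' processing notes. The aligner, the counting tool and their settings are not given in the sources used here. The deposited table holds raw whole-number counts of reads per miRNA and library, with no normalization, as read from its values. No reference genome of that build was used here.

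The table has 1703 rows: 1001 carry a miRNA name and 702 are predicted loci named by position. The predicted loci held 0.137 to 1.82% of counts in a library. Of these, 474 had counts in 1 library only and 15 in all 13, and they were left out of the main test. A mature miRNA made from several gene copies is listed more than once for 67 names, and the row with the highest total was kept, so that a read listed under every copy was not counted again. Pairs of names whose counts differed by at most 1% (with a total of at least 20) were merged, which applied to 3 pairs: miR-133a with miR-133c-3p, miR-199a with miR-199a-5p, and miR-500a-5p with miR-500b-5p. The handling of predicted loci and of names that share reads was chosen after seeing the table. This left 909 miRNAs, of which 297 had 0 counts in all libraries. Members of one family differ by few bases, and how the authors' counting divided their reads is not known, so values of single let-7, miR-30 or miR-133 members are uncertain.

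Counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood fit, robust, TMM factors, the filterByExpr filter), which kept 263 miRNAs holding at least 99.959% of each library's counts. The threshold was a Benjamini-Hochberg adjusted p of 0.05. TMM factors ran from 0.624 to 1.76. Levels are CPM (counts scaled to a fixed library size) with these factors, so that miR-486-5p is described by its share of counts instead. Log2 CPM used a prior count of 2. A count of 0 allows up to 3 counts, or 0.556 to 2.60 CPM before scaling, depending on the library. The pairs of libraries most alike within a group differed far beyond counting noise, with a chi-square per degree of freedom of at least 174, and every library was counted as 1 sample.

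Lists of miRNAs (19) were fixed before the data were examined: muscle-enriched, slow-fibre, let-7, miR-29, miR-30, DLK1-DIO3, miR-17/92, inflammation and senescence, insulin and lipid metabolism, muscle atrophy and hypoxia miRNAs, and markers of red blood cells, leukocytes, endothelium, fibroblasts, smooth muscle, epithelium, neurons and liver. The 15 with at least 3 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01, with an estimated correlation, and with fry, adjusted over the 15 lists. Some members belong to several lists: miR-486 is in the muscle-enriched, muscle atrophy and red blood cell lists, and miR-143-3p in the smooth muscle and metabolism lists. Shares of counts, the number of detected miRNAs and each list's mean level per sample were compared with two-sided exact permutation tests. These ran over the 1287 splits of 13 samples into 5 and 8, where the smallest p is 0.000777.

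The miRNAs named in the text follow a rule fixed before the data were examined: up to 10 raised and 10 lowered past the threshold, filled to 20 with the smallest unadjusted p, the muscle-enriched members with a mean of at least 100 CPM, the 5 most abundant, and the 2 members with the smallest p of each other tested list. Other miRNAs named as examples of a group or of Control replicate 4 were chosen after their values were seen. Alternatives were DESeq2 1.42.0, limma-voom, other scaling factors, other filters, the replicate number as a block, the sample number as a covariate, 1 surrogate variable (sva 3.50.0), summed copies, and leaving out each library. The test script was tested on simulated data, with 48 of the 263 miRNAs changed in each of 20 runs, where 4.63% of calls were false.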

Results

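Small RNA was sequenced from biopsies of the vastus lateralis, a thigh muscle, of rhesus monkeys on a control diet (5 samples) or on caloric restriction, abbreviated CR (8 samples). The series is titled for networks tied to the prevention by CR of sarcopenia, the loss of muscle with age, and the comparison made here asks which microRNAs (miRNAs) differed between the diets. Each library held 1154330 to 5392610 counts in 909 named miRNAs. The smallest library was CR replicate 1 and the largest CR replicate 6. Between 397 and 476 miRNAs had at least 1 count in a library. The labels do not say outright that each sample came from a different animal, and p-values here measure the spread between these samples.

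The miRNA with the most counts was miR-486-5p, which lies within the ankyrin gene ANK1 in the T2T-MMU8v2.0 annotation and is abundant in muscle and red blood cells. It took 54.3% ± 8.16 (SD, n = 5) of miRNA counts in Control and 59.5% ± 8.99 (SD, n = 8) in CR, with single libraries from 42.4% (Control replicate 4; 95% exact binomial interval 42.4 to 42.5%) to 70.7% (CR replicate 4; 70.7 to 70.8%). These intervals cover counting error only, and PCR copies of a read are not independent molecules. Abundance here means counts, which ligation and size selection can shift between miRNAs. The next largest shares of counts were those of miR-378a, encoded within a gene for a metabolic coactivator (8.22% ± 2.60 in Control, n = 5, and 7.50% ± 1.42 in CR, n = 8), miR-10b-5p (8.25% ± 5.20 and 7.22% ± 1.82), the muscle miRNA miR-133a (4.88% ± 2.01 and 4.74% ± 1.26) and the smooth muscle miRNA miR-143-3p (2.84% ± 1.56 and 2.28% ± 1.26; all SD). By edgeR the log2 fold changes of these 5 miRNAs, CR against Control, were 0.43 ± 0.34 (SE) for miR-486-5p, 0.0711 ± 0.31 for miR-378a, 0.16 ± 0.24 for miR-10b-5p, 0.19 ± 0.30 for miR-133a and -0.0870 ± 0.33 for miR-143-3p, each with an adjusted p of 0.985. With scaling to library totals alone, which moved the median log2 fold change of all miRNAs to -0.26 from 0.0103, the values of miR-378a, miR-10b-5p and miR-133a were -0.13, -0.19 and -0.0435. Without Control replicate 4 the 5 values were 0.25, -0.16, 0.32, -0.0509 and -0.0231. Over single libraries left out, that of miR-10b-5p ran from 0.0206 (without Control replicate 2) to 0.32 (without Control replicate 4). The rows of miR-133a and miR-133c-3p carried nearly the same reads and were counted as 1 miRNA.

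No single miRNA passed the threshold for a difference between CR and Control muscle. The smallest p belonged to miR-7174-5p, at 5.16 ± 2.54 CPM (SD, n = 8) in CR and 2.29 ± 0.62 (n = 5) in Control, and above the Control mean in 8 of 8 CR samples. The largest value in the other direction among the named miRNAs was that of miR-1247-3p, at 1.73 ± 1.42 CPM in CR and 5.15 ± 2.95 in Control, and below the Control mean in 8 of 8 CR samples. That mean includes 9.55 CPM in Control replicate 4. Without this library it was 4.05 ± 1.88 (SD, n = 4), 7 of 8 CR samples lay below it, and the miRNA no longer passed the filter on low counts. The log2 fold changes of miR-7174-5p and miR-1247-3p were 1.22 ± 0.40 (SE) and -1.51 ± 0.53, and edgeR gave both an adjusted p of 0.985. Of 263 miRNAs tested by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 passed. An unadjusted p under 0.05 was found for 7 (3 higher and 4 lower in CR), where 13.2 would be expected by chance. This count was 13, 11 and 14 without Control replicate 1, 3 and 5, and 11, 2 and 4 without CR replicate 2, 4 and 6. DESeq2 and limma-voom each called 0 as well, and each had 7 at the unadjusted threshold. The 95% interval of the fold change excluded a 2-fold change in either direction for 154 miRNAs (58.6%), and the median distance from the estimate to either end of its interval was 0.69 on the log2 scale. In counts simulated from these libraries, over the 263 miRNAs, the test recovered 12.5% of 1.5-fold, 42.5% of 2-fold, 84.6% of 3-fold and 92.1% of 4-fold changes. In each run 48 miRNAs were changed, every miRNA was drawn independently and no library was set apart. Measured miRNAs varied together within lists and Control replicate 4 lay apart, so these rates need not hold for the measured counts.

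The other miRNAs with an unadjusted p under 0.05 were miR-9-5p, a neuronal miRNA (log2 fold change 1.12 ± 0.44, SE), miR-489-3p, known from muscle satellite cells (1.01 ± 0.45), miR-130a-3p, an endothelial miRNA (-0.62 ± 0.29), and the DLK1-DIO3 locus miRNAs miR-381-3p (-1.16 ± 0.50) and miR-493-5p (-1.22 ± 0.55). The 13 that complete the set of 20 by p were let-7f-5p (0.43), miR-1-3p (0.91), miR-206 (0.65), miR-410-3p (-0.85), miR-365-3p (0.67), miR-433-3p (-0.90), miR-148a-3p (0.44), miR-98 (0.47), miR-29c-5p (0.61), miR-382-5p (-0.76), miR-30b-3p (0.78), miR-140-3p (-0.40) and miR-432-5p (-0.83). EdgeR gave each an adjusted p of 0.985. For miR-381-3p, miR-493-5p, miR-410-3p, miR-433-3p and miR-432-5p, 8 of 8 CR samples lay below the Control mean. That mean was set largely by Control replicate 4, where miR-381-3p stood at 881 CPM against 64.4 to 137 in the other Control samples. Without this library the log2 fold changes of miR-381-3p, miR-493-5p, miR-410-3p and miR-432-5p were 0.18, 0.10, 0.29 and 0.48. Those of miR-433-3p, miR-382-5p and miR-130a-3p were -0.0600, -0.20 and -0.29, and those of miR-140-3p, miR-29c-5p and miR-30b-3p were -0.26, 0.39 and 0.49. Without CR replicate 8 the value of miR-365-3p was 0.38, and without CR replicate 2 that of miR-140-3p was -0.61.

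**Figure D1:**
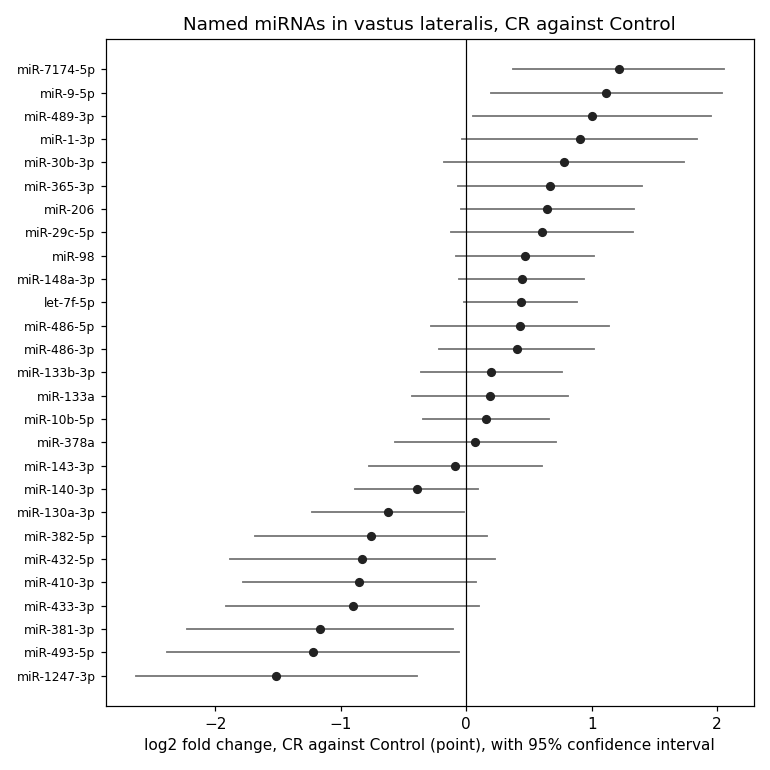
Log2 fold change, CR against Control, of the 20 miRNAs with the smallest p, the muscle-enriched miRNAs of high abundance and the 5 most abundant miRNAs (points), with 95% confidence intervals (lines; 5 Control and 8 CR samples). The values run from -1.51 for miR-1247-3p to 1.22 for miR-7174-5p, and none passed the adjusted threshold.

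The miRNAs of the DLK1-DIO3 locus, an imprinted region with a large miRNA cluster, stood lower in CR with all samples and higher in CR once Control replicate 4 was left out. With all 13 samples 23 of 25 members had a lower fitted level in CR, with a median log2 fold change of -0.48 (miR-127-3p -0.48 ± 0.37, SE; miR-411-5p -0.64 ± 0.40), and only miR-370-3p (0.32 ± 0.40) and miR-431 (0.17 ± 0.45) had a higher one. Without Control replicate 4, 23 of 25 members had a higher level in CR, with a median of 0.37 (miR-127-3p 0.39, miR-411-5p 0.23, miR-370-3p 0.62 and miR-431 0.89), and with 1 surrogate variable in the fit the median was 0.23. Without Control replicate 1 or Control replicate 5 it was -0.77. In Control replicate 4 miR-127-3p reached 10024 CPM against 1482 to 3242 in the other 12 libraries, and the mean level of the list was 5.66 log2 CPM against 3.33 to 4.10. Limma's camera test with a preset correlation between members gave an adjusted p of 0.00646 with all samples and 2.61e-06 without Control replicate 4. With an estimated correlation the adjusted p was 0.535 and 0.364 in turn. The 28 alternatives with the preset correlation ranged from 2.72e-08 to 0.112. Averaged per sample, the list's level was 3.89 ± 1.00 log2 CPM in Control (SD, n = 5) and 3.78 ± 0.27 in CR (n = 8), with a two-sided exact permutation p of 0.889 (adjusted over 15 lists, 0.902). Without Control replicate 4 the Control level was 3.44 ± 0.15 and the exact permutation p 0.0444 (adjusted 0.444). Adjusted over the list alone, 0 members passed in edgeR.

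Muscle-enriched miRNAs, which act in muscle differentiation and fibre identity, had higher fitted levels in CR for 8 of 9 members, with a median log2 fold change of 0.40. Among them were miR-1-3p, at 216 ± 128 CPM in CR (SD, n = 8) and 116 ± 58.6 in Control (n = 5), miR-206, at 2905 ± 925 and 1856 ± 940, miR-133b-3p, with a log2 fold change of 0.20 ± 0.27 (SE), and miR-486-3p, with 0.40 ± 0.30. Camera with the preset correlation gave an adjusted p of 0.00855, the adjusted p was 0.352 with an estimated correlation, and 0 members passed adjusted over the list alone. For the list's mean level per sample the two-sided exact permutation p was 0.418 (adjusted over 15 lists, 0.693). The call was also lost with the sample number as covariate, with 1 surrogate variable and with the replicate number as a block. Control replicate 4 held the lowest level of this list, at 7.09 log2 CPM against 8.55 to 9.64 in the other libraries, with miR-206 at 570 CPM and miR-1-3p at 28.9. Without CR replicate 1 the median was 0.16, and the list still passed. Without Control replicate 4 the median was 0.17, with log2 fold changes of 0.66 ± 0.42 for miR-1-3p, 0.42 ± 0.27 for miR-206, 0.17 for miR-486-3p, -0.0202 for miR-133b-3p and -0.0509 for miR-133a, and camera's adjusted p was 0.913 with its direction turned. As a share of counts these miRNAs took 64.6% ± 8.05 in CR (n = 8) and 59.5% ± 9.08 in Control (n = 5), with a two-sided exact permutation p of 0.309 (adjusted over 4 measures, 0.459). The difference of 5.12 percentage points was 1.45 without Control replicate 4 and 7.30 without Control replicate 1. Leaving out miR-486, which red blood cells also hold, the others took 5.13% of all miRNA counts in CR and 5.18% in Control. This difference of -0.0519 percentage points keeps miR-486 in the total, so its larger mean share in CR lowers that of the others. A share out of the counts without miR-486 was not computed. The slow-fibre members miR-208b-3p and miR-499-5p, too few for a list test, had log2 fold changes of 0.71 ± 0.95 and 0.20 ± 0.84. Over single libraries left out these ran from -0.36 (without CR replicate 1) to 1.02 (without Control replicate 1) and from -0.13 (without CR replicate 7) to 0.61 (without Control replicate 5).

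Markers of other cell types in the biopsies were also compared. All 4 fibroblast miRNAs had lower fitted levels in CR (median -0.42; miR-199a -0.45 ± 0.32 and miR-214-5p -0.49 ± 0.39, SE). They are both arms of miR-199a and of miR-214, with an estimated correlation of 0.92, and are not independent markers. Of the endothelial miRNAs, 5 of 6 were also lower in CR (median -0.21; miR-130a-3p -0.62 ± 0.29 and miR-424-3p -0.40 ± 0.46). The 3 neuronal miRNAs, miR-9-5p and both arms of miR-129, had higher fitted levels in CR (median 0.61; miR-9-5p 1.12 ± 0.44 and miR-129-2-3p 0.61 ± 0.86). Camera's adjusted p with the preset correlation was 0.0121, 0.0225 and 0.0400 for these lists, and the adjusted p was 0.352 for each with an estimated correlation. For the lists' mean levels per sample, the two-sided exact permutation p was 0.315, 0.239 and 0.216 in turn (adjusted over 15 lists, 0.693 for each). Control replicate 4 held the highest fibroblast and endothelial and the lowest neuronal levels, and without it the medians were -0.0940, -0.11 and 0.29, with adjusted p values of 0.329, 0.301 and 0.301. The neuronal median was -0.23 without CR replicate 4 (adjusted p 0.182) and -0.43 with no filter on low counts. Over 27 alternatives that list's adjusted p ran from 0.00174 to 0.872. Further medians were 1.53 and 0.36 (neuronal, without Control replicate 1 and 5), -0.70 and -0.68 (fibroblast, without Control replicate 5 and CR replicate 2) and -0.32, -0.34 and -0.42 (endothelial, without Control replicate 2, Control replicate 5 and CR replicate 2). Of the members named, miR-199a and miR-214-5p were at -0.13 and -0.17 without Control replicate 4, at -0.68 and -0.77 without Control replicate 5, and at -0.68 and -0.81 without CR replicate 2. The value of miR-130a-3p was -0.29 without Control replicate 4. That of miR-424-3p was -0.14, -0.26 and -0.62 without Control replicate 1, 3 and 4, and that of miR-129-2-3p ran from -0.23 (without CR replicate 4) to 1.88 (without Control replicate 1). The neuronal call was also lost without Control replicate 2, 3 or 5, the fibroblast call without Control replicate 2, and the endothelial call without Control replicate 3, Control replicate 5 or CR replicate 1. All of these calls were lost with 1 surrogate variable or with the replicate number as a block. With the sample number as covariate or with library totals alone the fibroblast call was lost. The neuronal list was not called with DESeq2, with summed copies, with no filter on low counts or with a mean CPM of at least 10. The lists of leukocytes (median -0.15 over 7; miR-223 -0.71 ± 0.54, miR-342-3p 0.39 ± 0.26), smooth muscle (-0.0870 over 3; miR-143-3p, miR-145-5p -0.26 ± 0.31) and red blood cells (0.40 over 3; both arms of miR-486, with miR-451 at -0.16 ± 0.55) did not pass, with camera adjusted p of 0.213, 0.345 and 0.213. The value of miR-342-3p was 0.11 without CR replicate 8 and 0.23 without Control replicate 5, and those of miR-223 and miR-145-5p were -0.34 and -0.0814 without Control replicate 4. The last was -0.47 without CR replicate 5. The share of counts in miR-451 and miR-144, red blood cell miRNAs, was 0.0608% ± 0.0365 in CR (n = 8) and 0.0852% ± 0.0467 in Control (n = 5; two-sided exact permutation p 0.308, adjusted 0.459). The difference of -0.0243 points was -0.0128, -0.0136 and -0.0410 without Control replicate 4, 5 and 2. The liver miRNA miR-122a-5p had a log2 fold change of -1.17 ± 0.77 (0.39 without Control replicate 5), and no epithelial marker was among the miRNAs tested.

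**Figure D2:**
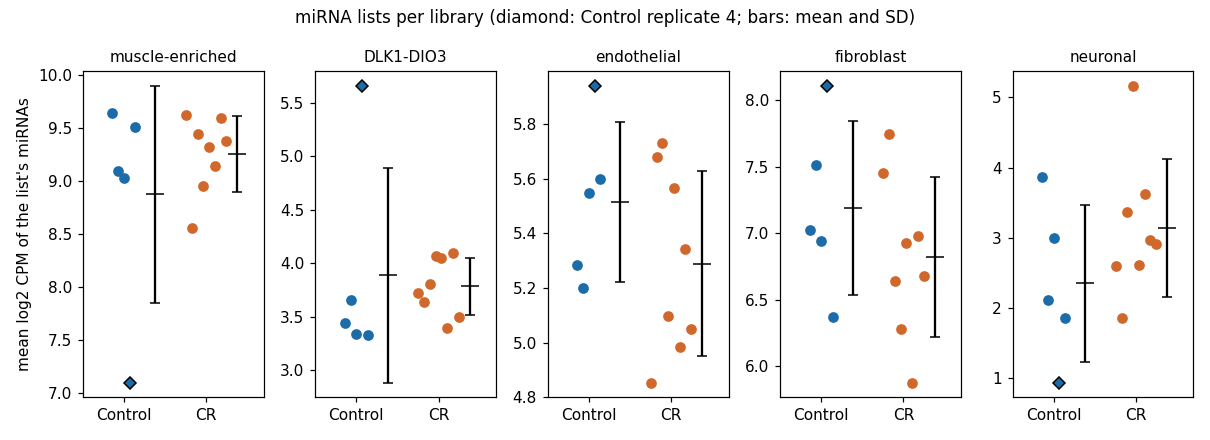
Mean log2 CPM of the miRNAs of 5 lists in each library (y axis, separate scale per panel), for 5 Control (blue) and 8 CR (orange) samples, with the mean and SD of each group as black bars and Control replicate 4 as a diamond. Control replicate 4 lies at 5.66 for the DLK1-DIO3 list and at 7.09 for the muscle-enriched list, outside the range of all other libraries in each of the 5 panels.

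Other groups tied to diet, ageing or metabolism did not pass in the main test. The let-7 and miR-30 miRNAs each did under 6 of 28 alternatives, miR-17/92 miRNAs under 5, muscle atrophy miRNAs under 2 and insulin and lipid metabolism miRNAs under 1. Among let-7 family miRNAs, which repress growth pathways, 10 of 14 had higher levels in CR (median 0.15; let-7f-5p 0.43 ± 0.21, above the Control mean in 8 of 8 CR samples, and miR-98 0.47 ± 0.26, SE), with a camera adjusted p of 0.0665. The miR-30 family gave a median of 0.15 with 8 of 11 higher (miR-30b-3p 0.78 ± 0.46, miR-30d-3p 0.46 ± 0.35; 0.0665), and the miR-29 family, which targets collagen transcripts, 0.13 with 2 of 3 higher (miR-29c-5p 0.61 ± 0.35, miR-29a-3p -0.14 ± 0.22; 0.463). Insulin and lipid metabolism miRNAs had a median of 0.17 with 9 of 12 higher (miR-365-3p 0.67 ± 0.35, miR-27a-3p 0.41 ± 0.25; 0.0900), and muscle atrophy miRNAs 0.17 with 7 of 10 higher (miR-206 and miR-27a-3p; 0.113). All 9 members of the miR-17/92 and related clusters had lower levels in CR (median -0.0959; miR-18a-3p -0.31 ± 0.51, miR-19b -0.26 ± 0.54; 0.202). Inflammation and senescence miRNAs had a median of 0.0854 and a mean of 0.0519, while camera gave the direction as down (miR-146b-5p -0.27 ± 0.30, miR-22 0.22 ± 0.26; 0.916). With scaling to library totals alone the let-7, miR-30, miR-29, muscle atrophy and inflammation medians were -0.15, -0.0303, -0.16, -0.0290 and -0.14, with camera's direction unchanged. Single libraries also moved these medians. That of let-7 ran from 0.00638 (without Control replicate 5) to 0.25 (without Control replicate 2), and that of muscle atrophy miRNAs from 0.00731 (CR replicate 1) to 0.33 (Control replicate 2). Insulin and lipid metabolism miRNAs ran from 0.0498 (Control replicate 4) to 0.26 (Control replicate 2), and miR-27a-3p was at 0.16 without CR replicate 1. The miR-30 and miR-29 medians were -0.0404 and -0.10 without Control replicate 4, and the miR-17/92 median was 0.0449 without Control replicate 5. Without Control replicate 4 the values of miR-30d-3p, miR-29a-3p, miR-146b-5p and miR-22 were 0.27, -0.26, 0.19 and 0.0257, and miR-22 was at 0.0977 without CR replicate 6. Without Control replicate 5 those of miR-18a-3p and miR-19b were 0.00578 and 0.10. The hypoxia miRNA miR-210 had log2 fold changes of 0.52 ± 0.47 (5p) and 0.34 ± 0.32 (3p). The first was 0.95, 0.28 and 0.34 without Control replicate 2, 4 and 5, and 0.31 and 0.23 without CR replicate 4 and 8. The second was 0.18 and 0.16 without Control replicate 3 and 4, and 0.21 without CR replicate 3. With an estimated correlation, and with fry, 0 of the 15 lists passed, and adjusted over the list alone 0 members passed in any of them. In two-sided exact permutation tests of the lists' mean levels per sample, the smallest p was 0.0303, for muscle atrophy miRNAs (adjusted over 15 lists, 0.455).

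The breadth of the miRNA counts differed by less than the spread between samples. The 5 most abundant miRNAs held 81.2% ± 4.91 of counts in CR (SD, n = 8) and 78.5% ± 4.82 in Control (n = 5; two-sided exact permutation p 0.344, adjusted 0.459). The difference of 2.73 points was 0.81 without Control replicate 4 and 4.07 without CR replicate 1. The number of miRNAs detected was 427.3 ± 23.9 in CR (n = 8) and 432.6 ± 31.0 in Control (n = 5; exact permutation p 0.722, adjusted 0.722). The difference ran from -13.75 (without Control replicate 5) to 5.5 (without Control replicate 4).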

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

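The tests on predicted loci, on correlated list members and on the count past the adjusted threshold were chosen after the result was seen. Outliers were sought in 132 groups of values, where chance flags about 1 in 20 (6.6), and 20 were found, 16 of them in Control replicate 4. Lists were searched beside their own members in the same libraries, so the flags of a library are not independent of each other.

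Control replicate 4 lay apart from the other 4 Control samples in DLK1-DIO3 miRNAs: miR-381-3p was at 881 CPM (others 64.4 to 137), miR-410-3p at 426 (39.5 to 75.8), miR-382-5p at 18.2 (5.26 to 6.16), and the list's mean at 5.66 log2 CPM (3.33 to 3.66). It was also higher for miR-146b-5p, at 1217 CPM (328 to 471). It was lower for muscle miRNAs: miR-133a at 12644 CPM (48173 to 55769), miR-133b-3p at 289 (832 to 1100), miR-1-3p at 28.9 (112 to 194), miR-208b-3p at 0.245 (5.04 to 11.6), miR-486-3p at 104 (342 to 477), and the muscle-enriched list at 7.09 log2 CPM (9.03 to 9.64). Further low values were miR-378a at 23011 CPM (71490 to 109967), miR-22 at 4671 (11461 to 14251), miR-29c-5p at 2.94 (7.91 to 9.52), the miR-30 family at 6.38 log2 CPM (7.58 to 7.97) and the insulin and lipid metabolism miRNAs at 8.00 (8.68 to 8.93).

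Explanations for Control replicate 4 were weighed as follows. Sequencing depth is argued against: after all libraries were thinned to the smallest total its mean Spearman correlation with the others was 0.903, where the lowest of the others was 0.932. More fibroblast-rich tissue in that biopsy may be part of it, since the fibroblast markers lay 1.24 log2 units above the mean of the other 12 libraries and above the highest (7.75 log2 CPM). These 4 miRNAs are both arms of miR-199a and of miR-214 and are not independent markers. They are also detected in the other muscle libraries, the most abundant, miR-199a-3p, at 289 to 898 CPM against 1055. A lower share of muscle fibres stays open, with 3 of 4 lists of other cell types above all other libraries and smooth muscle within their range. Against markers of every other type being raised, the neuronal list lay 2.06 log2 units below the mean of the other 12 and below all of them, but this rests on the arms of miR-129, near the detection floor at 0.612 and 0.857 CPM, with miR-9-5p within the range. Also open is more blood in that biopsy, with miR-451 0.46 log2 units above the mean but inside the range of the others. Its share of counts in miR-451 and miR-144 was the highest of all libraries, at 0.131% (next, Control replicate 5 at 0.128%). By contrast miR-486-5p, which muscle also holds, had its lowest share of counts there, at 42.4% (next, CR replicate 1 at 44.6%). Shares are not scaled, while the CPM of miR-451 uses the TMM factor. That factor was highest in Control replicate 4, at 1.76, which lowers its CPM against its shares. The design names no difference among Control samples, so no explanation by its groups was tested.

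For the 7 miRNAs at an unadjusted p under 0.05 chance cannot be excluded, since 80 of 100 splits of the samples gave at least as many (median 12, highest other split 37). The 0 miRNAs past the adjusted threshold cannot be tested in this way: all 100 splits reach a count of 0 by construction (highest other split, 2).

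The 5 lists called with a preset correlation were weighed in the same way. Of 100 splits, 15 gave at least 5 lists (highest other split, 7), so chance cannot be excluded. Members of a list varying together between animals may account for the calls, since 0 lists passed with an estimated correlation. Control replicate 4 alone stays open as an account of all 5 calls. Without it 1 of the 5 lists passed, that of the DLK1-DIO3 locus, in the opposite direction, while the other 4 did not pass. For the DLK1-DIO3 list the lower level in CR rested on Control replicate 4. Its median log2 fold change was -0.48 with that library and 0.37 without it. None of the 5 calls was thus kept in its own direction without that library. Diet stays among the open explanations.

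Among the remaining outliers, miR-27a-3p stood at 601 CPM in CR replicate 1 (other CR samples 211 to 294), and its log2 fold change was 0.16 without that library in place of 0.41. In the same library miR-424-3p stood at 0.562 CPM (3.18 to 8.32). This lies under the 2.60 CPM, before scaling, that a count of 0 allows in that library, so its distance from the others is uncertain. In CR replicate 8, miR-342-3p stood at 165 CPM (64.7 to 88.4), with a log2 fold change of 0.11 without it in place of 0.39. In Control replicate 5 the liver miRNA miR-122a-5p stood at 24.2 CPM (other Control samples 1.68 to 2.32), and without that library its log2 fold change was 0.39 in place of -1.17.

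Outside the named miRNAs, 3 predicted loci had at least 10000 counts in a CR library and 0 in all Control libraries. The locus on chromosome 4 from 113958141 to 113958195 (Mmul_8.0.1) held 46063 counts in CR replicate 7 and 0 elsewhere. The mitochondrial locus from 10344 to 10391 and one on an unplaced scaffold, from 125 to 172, held identical counts, with 18051 in CR replicate 5, 14115 in CR replicate 6 and 4082 in CR replicate 3. Loci may have been listed separately for each library, so that a 0 is a missing entry. Where 20 or more reads were expected from the mean rate of the other libraries, 45.4% of entries of predicted loci were 0, against 0.0359% for named miRNAs. A locus truly read in a single library would give such zeros too, so this percentage alone cannot tell a missing entry from a true 0. Some abundant loci held values that argue against a true 0 there. A locus on chromosome 8, from 92447795 to 92447853, held 1726 to 5072 counts in 12 libraries and 0 in CR replicate 1. The most abundant locus held 5381 to 47172 in 8 libraries and 0 in the others. By contrast, 15 predicted loci had counts in all 13. Loci listed in few libraries, such as the 3 above, are not covered by these values. Diet stays open for these 3 loci, which were picked for being at 0 in Control and were listed in 1, 3 and 3 of 8 CR libraries. The most abundant predicted locus, at 0 in some libraries of both diets (two-sided exact Fisher p = 1), is not one of them and decides nothing about diet for them.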

How the results depend on the processing

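The refits with names that share reads kept apart, with predicted loci included and with 2 libraries left out together, and the muscle-enriched share without miR-486, were chosen after seeing the data; the other alternatives were fixed before. The count of miRNAs past the adjusted threshold was 0 under all 28 refits, with 2 to 28 at an unadjusted p under 0.05. These were 28 of 612 tested with no filter on low counts, 12 of 263 with library totals alone and 2 of 182 with a mean CPM of at least 10. The number tested differs between these settings, so the counts are not directly comparable. A pseudocount was not varied because the table holds counts. Directions below are of single miRNAs' log2 fold changes and, for lists, of camera, with the median log2 fold change as the value; the cause of each turn was not tested except where a left-out library shows it.

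The replicate numbers do not pair the samples: correlations of same-numbered deviations were -0.24, -0.10, -0.0608, -0.0474 and -0.16, and no Control sample correlated best with its own number. With the replicate number as a block 0 miRNAs and 0 lists were called, and these turned: miR-432-5p 0.0178, miR-378a -0.00875, miR-143-3p 0.0295, the miR-29 family -0.11 and inflammation miRNAs 0.12.

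The number of lists called, 5 in the main test, was 0 with an estimated correlation or with fry. It was 3 with 1 surrogate variable (let-7, miR-17/92 and DLK1-DIO3, of which only the last, turned, is among the 5) and 1 with Control replicate 4 and CR replicate 1 both left out (DLK1-DIO3, turned). Leaving out single libraries gave 1 (without Control replicate 4; DLK1-DIO3, turned) to 8 (without Control replicate 1 or CR replicate 6, in each case the 5 and 3 others). With the sample number as covariate 6 lists were called: the muscle-enriched and fibroblast calls were lost, and let-7, miR-17/92 and muscle atrophy miRNAs were gained. The sample number partly follows diet (mean 4.4 in Control and 8.6 in CR), so its effect and that of diet are only partly separable.

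Lists not called in the main test passed under some of 28 alternatives: let-7 under 6 (lowest adjusted p 0.0307, highest 0.493), miR-30 under 6 (0.00571 to 0.918), miR-17/92 under 5 (0.0274 to 0.692), muscle atrophy under 2 (0.0356 to 0.692), insulin and lipid metabolism under 1 (0.0401 to 0.942) and red blood cell under 1 (0.0498 to 0.966). Of the 5 called lists over single libraries left out, the neuronal median ran from -0.23 (without CR replicate 4) to 1.53 (without Control replicate 1). The fibroblast median ran from -0.70 (Control replicate 5) to -0.0940 (Control replicate 4) and the endothelial from -0.42 (CR replicate 2) to -0.11 (Control replicate 4). The difference in share of muscle-enriched miRNAs was -0.0519 points with miR-486 left out of them but kept in the total. The difference in miRNAs detected ran from -13.75 to 5.5 over single libraries left out, turning without Control replicate 4. Differences in share ran from 1.45 to 7.30 points for muscle-enriched miRNAs, from 0.81 to 4.07 for the 5 most abundant and from -0.0410 to -0.0128 for miR-451 and miR-144. The let-7 median ran from 0.00638 to 0.25, muscle atrophy from 0.00731 to 0.33, red blood cell from 0.17 to 0.54, leukocyte from -0.26 to -0.0269 and smooth muscle from -0.29 to 0.00275.

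With upper-quartile factors miR-378a turned to -0.00275. With library totals alone miR-133a was -0.0435, miR-378a -0.13, miR-10b-5p -0.19 and miR-342-3p -0.0375, and the let-7, muscle atrophy, miR-29, miR-30 and inflammation medians were -0.15, -0.0290, -0.16, -0.0303 and -0.14, with camera's direction unchanged. With no low-count filter the miR-29 family was 0.0725, inflammation miRNAs 0.0261 and neuronal miRNAs -0.43. With DESeq2 inflammation miRNAs were 0.0345. With the sample number as covariate miR-378a was -0.22, miR-10b-5p -0.0998, the miR-29 family -0.0965 and inflammation miRNAs 0.0758. With 1 surrogate variable miR-410-3p was 0.15, miR-432-5p 0.29, miR-378a -0.0686, miR-146b-5p 0.0764, the miR-29 family -0.13, the miR-30 family 0.0390, DLK1-DIO3 miRNAs 0.23 and inflammation miRNAs 0.11.

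With Control replicate 4 and CR replicate 1 both left out, miR-381-3p was 0.24, miR-493-5p 0.0571, miR-410-3p 0.22, miR-432-5p 0.41, miR-133a -0.0602, miR-133b-3p -0.0566, miR-378a -0.0935, miR-143-3p 0.0151, miR-146b-5p 0.21, miR-22 -0.00558, miR-208b-3p -0.74 and miR-499-5p -0.51. Among lists, muscle-enriched miRNAs were -0.0566, miR-29 -0.0331, miR-30 -0.10, DLK1-DIO3 0.33, insulin and lipid metabolism -0.0224, leukocyte -0.0783 and smooth muscle 0.0151.

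Leaving out single libraries, with the turn at the library named, miR-381-3p ran from -1.52 to 0.18, miR-493-5p from -1.59 to 0.10, miR-410-3p from -1.22 to 0.29, miR-432-5p from -1.21 to 0.48, miR-133a from -0.0509 to 0.28, miR-133b-3p from -0.0202 to 0.31, miR-378a from -0.16 to 0.20 and miR-146b-5p from -0.51 to 0.19 (Control replicate 4; miR-378a also CR replicate 8). miR-143-3p ran from -0.29 to 0.11 (Control replicate 5 and CR replicate 4), miR-18a-3p from -0.60 to 0.00578, miR-19b from -0.53 to 0.10 and miR-122a-5p from -1.61 to 0.39 (Control replicate 5). miR-29a-3p ran from -0.26 to 0.0132 (Control replicate 3), miR-208b-3p from -0.36 to 1.02 (CR replicate 1), miR-129-2-3p from -0.23 to 1.88 (CR replicate 4) and miR-499-5p from -0.13 to 0.61 (Control replicates 3 and 4, CR replicates 1 and 7). Among lists, DLK1-DIO3 ran from -0.77 to 0.37, muscle-enriched miRNAs from 0.16 to 0.54, miR-29 from -0.10 to 0.27, miR-30 from -0.0404 to 0.23 and insulin and lipid metabolism miRNAs from 0.0498 to 0.26 (Control replicate 4), miR-17/92 from -0.27 to 0.0449 (Control replicate 5) and inflammation miRNAs from -0.0357 to 0.12 (Control replicates 2 and 4, CR replicates 2, 3, 4, 6 and 8). At 1154330 counts in the smallest library, depth limits values of a few CPM.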

Other observations

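The DLK1-DIO3 miRNAs varied as a block in 1 Control library. In Control replicate 4, 23 of the 25 tested members lay above all 12 other libraries, and the median over all 25 was 4.23 times the geometric mean of the others. In that library the 10 miRNAs farthest above the other libraries were all members. miR-1247-3p, which was outside the list, lay above all other libraries there too, at 9.55 CPM against at most 5.88, while the other arm, miR-1247-5p, at 41.3 CPM, lay within their range (5.06 to 51.3). In the reference annotation T2T-MMU8v2.0 the gene of miR-1247 lies between DLK1 and DIO3, and 21 of the 22 precursors of the list were found, all 21 in the same interval. The miRNAs farthest below the other libraries in Control replicate 4 were the slow-fibre miRNA miR-499-5p (0.367 CPM against a mean of 11.95), miR-129-5p and miR-208b-3p. These stood near the detection floor in that library, so their distances and their order are uncertain. In total 52 tested miRNAs lay above and 73 below all other libraries, where an even spread over the 13 libraries gives 20.2 of each. CR replicate 8 had 33 and 43, CR replicate 1 had 37 and 21, Control replicate 5 had 27 and 26, and CR replicate 2 had 25 and 7.

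miR-1-3p, a partner of miR-133a in shared muscle transcripts, averaged 178 CPM here against 48853 CPM for miR-133a and 2501 CPM for miR-206. Ligation and size selection differ between miRNAs and the counting tool is not given, so levels of different miRNAs in a library are not a measure of their relative amounts.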
